A study of Homo sapiens with 9 samples.

How the data were processed

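The material was NCI-H441, an established lung adenocarcinoma cell line, treated for 48 hours with 20 nM of a negative control siRNA or of 1 of 2 siRNAs against RIPK3. The cells were then left unstimulated, given TNF at 10 ng/mL, or given the mix called TZB, in which zVAD-fmk at 20 µM and birinapant at 100 nM preceded the same dose of TNF by 1 hour, per the labels' protocols. RNA was taken with a Qiagen RNeasy kit, and 1.0 µg of total RNA entered a directional NEBNext Ultra II preparation, per the labels' protocols. There were 9 libraries, 1 for each pairing of siRNA and stimulation. The time from stimulation to harvest and the step that removes or selects RNA before the library were not given in the sources used here. Each library was placed in its group by its title and characteristics. No combination has a second library, so p-values measure only the spread that the siRNA and stimulation terms leave unexplained. An SD of 3 libraries spans the 3 siRNAs or the 3 stimulation states, not replicates. The labels do not say that libraries came from separate cultures, so part of the spread may be technical.

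The authors deposited 1 table per library with 61552 human genes, their Ensembl identifiers, coordinates and several measures. The deposited counts are whole reads or read pairs per gene, per the file headers: total and unique gene reads, the exon and intron reads they are made of, and reads that span 2 exons. The authors also deposited TPM values, listed under 2 names with the same numbers, and RPKM values, per the file headers. A further 2 deposited columns hold a fraction each, per the file headers: unique over total exon reads, and intron over total gene reads. Only the counts entered tests. The aligner, the counter and whether counting used strand were not given in the sources used here. Builds named in the submitters' processing notes were GRCm38, mm10 and hg38, of which the first 2 are mouse builds. The coordinates in the files are those of GRCh38: 58352 of the genes are also in GENCODE release 29, and 99.9% of those overlap their position there (72.5% with the same start and end). Because strand use was not given, overlapping and antisense genes are reported as uncertain.

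Total gene reads came to 21241362 to 30765789 per library (median 26554698), of which 94.5% to 95.0% were unique, 3.13% to 4.70% fell in introns and 2.27% to 4.26% in mitochondrial genes. The 10 most abundant genes took 4.57% to 5.34%. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 13.2). For genes above 10 CPM the median standard error was 0.0730 log2 units for a stimulation effect and 0.149 for the interaction of TZB and knockdown.

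Total gene reads were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, genes kept by filterByExpr with stimulation as the group (minimum count 10), and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The model had terms for siRNA (3 levels) and stimulation (3 levels) and 4 residual degrees of freedom. CPM stands for reads scaled to library size with TMM factors. Contrasts were TNF or TZB against no stimulation, TZB against TNF, the RIPK3 siRNAs against the control (mean and each alone), and 1 RIPK3 siRNA against the other. A second model added knockdown by stimulation terms and had 2 residual degrees of freedom, which come from the 2 RIPK3 siRNAs differing in their responses. Levels are TMM-scaled reads as CPM. The standard error of a log2 fold change is its size over the square root of its F statistic. Intervals on reads are exact 95% Poisson intervals, and intervals and floors cover counting error only. A fold against a group with 0 reads was computed against a floor of 3 reads over the group.

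The siRNA term works as a replicate block, since RIPK3 siRNAs with the same number in the labels are the same reagent. The series themselves hold different siRNAs, so they are not replicates of a condition. Across 13818 genes, which are not independent replicates, the difference between RIPK3 siRNA 1 and 2 correlated between states at 0.61 (no stimulation and TNF), 0.623 (no stimulation and TZB) and 0.575 (TNF and TZB). The fit with no replicate block joined both RIPK3 siRNAs into 1 group.

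A total of 28 gene lists (753 entries, covering 589 different tested genes) were written from general knowledge of the cell type, the stimuli, cell death, stress, RNA quality and other cell types. Of these 27 had at least 5 tested members and were tested per contrast with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether a list's genes move one way without comparing them with other genes. Counts of list members are given over all genes tested and adjusted over the list alone. Some genes are in more than 1 list, such as BIRC3 (NF-κB targets and necroptosis) and ICOSLG (NF-κB targets and immune surface molecules). The lists are therefore not separate findings. The members of 1 list, and some single genes, are not reported here.

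Genes to name were set by a rule. RIPK3, MLKL, RIPK1, ZBP1, CASP8, TNFAIP3, NFKBIA, CXCL8 and BIRC3 were always named. For the main contrasts the 6 highest and 6 lowest fold changes were added among genes that passed, had a mean of at least 1 CPM and a proper symbol, and moved the same way with every siRNA (or in every matched pair of libraries). Where none passed, up to 3 genes of smallest p in each direction are given as not passing. For each list, up to 4 members with the smallest p are named. The lists, this rule, the models and the alternatives below, except those named as added, were fixed before the data were examined.

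Alternatives were RLE and upper-quartile scaling, no filter on low counts, DESeq2 1.42.0, uniquely placed reads, no replicate block, a minimum absolute log2 fold change of 1, only the 6 libraries of the states compared, and leaving out each library and each siRNA series. Chosen after seeing the data were exon reads only, no mitochondrial genes, leaving out the 2 libraries of lowest mitochondrial share, and counting only genes without a sequence match to any siRNA. Overlaps that share control libraries were compared with 20 simulations of unchanged groups. For sequence matches, 15566 7-mers were counted in the 3' untranslated regions of 9463 genes above 10 CPM (98.8% of 9578 such coding genes). For each siRNA the log2 difference of a gene from the mean of the other 2 siRNAs was taken, and for TNF and TZB that from no stimulation. Differences were capped at an absolute value of 2. Each 7-mer was scored by a z for the relation of its presence to these differences. The z was adjusted for the length and base content of the region and for mean CPM. The range without any match came from 100 permutations of genes.

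The fits were tested on simulated counts with 200 changed genes and no other siRNA or stimulation effect. For TZB against no stimulation 76%, 84%, 100.0% and 100.0% of genes changed 1.5, 2, 4 and 8-fold were recovered, with 12 of 192 calls wrong. For the RIPK3 siRNAs against the control it was 90.0%, 80.0%, 100.0% and 100.0% (9 of 194 wrong), and for the interaction of TZB and knockdown 32%, 82%, 90.0% and 92% (22 of 170 wrong). The 7-mer search ranked each of 5 planted 7-mers lowest of all. Each lowered its genes by 0.3 log2 units, and smaller falls were not planted. In the real data the lowest 7-mer of RIPK3 siRNA 2 had median differences of -0.228 with it and 0.001 without it. For the control siRNA these were -0.075 and 0.023, so recovery at such sizes was not tested. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.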

Results

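Gene expression was measured by RNA sequencing of total RNA in 9 libraries of NCI-H441, a human lung adenocarcinoma line that expresses surfactant genes of alveolar type 2 cells. The cells carried 1 of 3 siRNAs (a negative control, RIPK3 siRNA 1 or RIPK3 siRNA 2, each at 20 nM for 48 hours) and received 1 of 3 stimulation states, which makes 1 library for each of the 9 combinations. The states were no stimulation, TNF alone at 10 ng/mL, and a mix called TZB here. TZB held the same dose of TNF with zVAD-fmk, a caspase inhibitor, at 20 µM and birinapant, which mimics SMAC and removes IAP proteins, at 100 nM. Per the labels it induces necroptosis, a lytic cell death that runs through the kinases RIPK1 and RIPK3 and the pore-forming protein MLKL. Libraries held 21241362 to 30765789 reads in genes. Of the 61552 annotated genes, 16423 had enough reads to be tested. Stimulation effects were averaged over the 3 siRNAs (n = 3 libraries per state) and siRNA effects over the 3 states (n = 3 libraries per siRNA). Across the 13818 genes with a mean of at least 1 CPM, 38.6% of the variance lay between siRNAs, 39.8% between stimulation states and 21.6% in neither.

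RIPK3, the targeted kinase (ENSG00000129465, chromosome 14, 24336025 to 24340022, minus strand, GRCh38), was read first as a check of the labels. It had 192, 219 and 110 reads in the negative control libraries without stimulation, with TNF and with TZB, with 95% Poisson intervals of 165.8 to 221.2, 191 to 250 and 90.4 to 132.6. RIPK3 siRNA 1 left 27, 12 and 30 reads, and RIPK3 siRNA 2 left 10, 15 and 8. After scaling, siRNA 1 left 19.2%, 5.22% and 21.7% of the level in the control library of the same state, and siRNA 2 left 4.77%, 5.39% and 5.49%. The mean fall was -3.53 ± 0.28 on the log2 scale (SE; adjusted p = 7.33e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By siRNA it was -2.84 (adjusted p = 1.37e-04) and -4.23 (adjusted p = 1.89e-05). RIPK3 itself did not pass with TNF (log2 0.12 ± 0.36, adjusted p = 0.886) or with TZB (-0.15 ± 0.37, adjusted p = 0.814). Both values average over series in which RIPK3 was silenced, and with TNF the series ran from -1.31 to 0.67. They cannot show whether stimulation changes RIPK3 in unsilenced cells. The control libraries, 1 per state, stood at 6.51 CPM without stimulation, 9.40 with TNF and 5.42 with TZB.

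**Figure D1:**
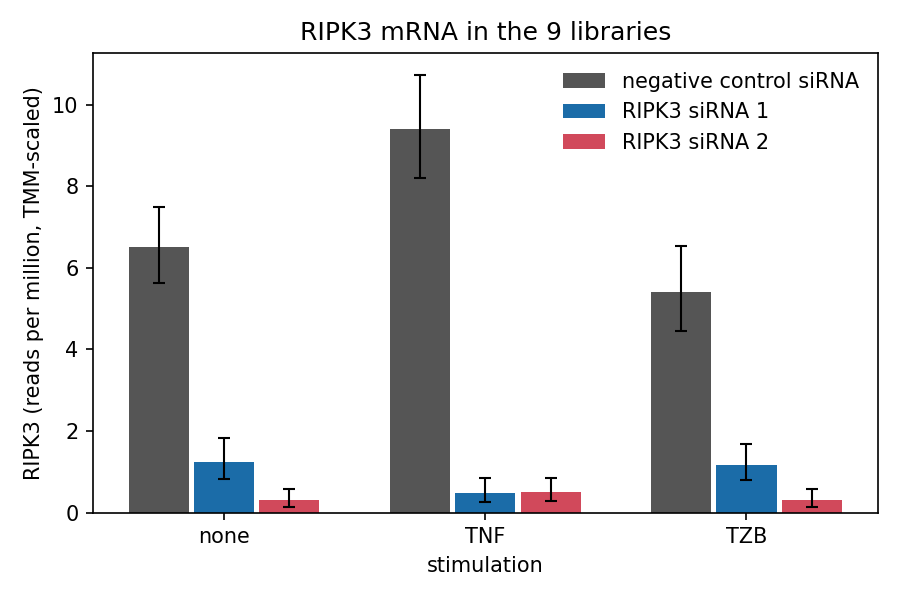
RIPK3 in each of the 9 libraries, in TMM-scaled CPM (vertical axis) by stimulation state (horizontal axis) and siRNA (colour). Bars are single libraries and error bars are 95% Poisson intervals for counting error only. The 3 control libraries lie between 5.42 and 9.40, and the 6 libraries with a RIPK3 siRNA lie between 0.298 and 1.25.

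The comparison of TNF with no stimulation asked how the cells respond to the cytokine. TNF raised the genes that NF-κB is known to drive. BIRC3, which encodes the ubiquitin ligase cIAP2, went from 51.8 ± 11.1 to 405.1 ± 90.6 CPM (SD, n = 3), a log2 fold change of 2.96 ± 0.07 (SE). The feedback inhibitors TNFAIP3 (A20) and NFKBIA (IκBα) rose by 2.72 ± 0.07 and 2.44 ± 0.06, and the neutrophil chemokine CXCL8 rose by 2.40 ± 0.14. The highest fold changes among named genes were those of OR2I1P (6.42 ± 0.15), the monocyte chemokine CCL2 (5.43 ± 0.31), lymphotoxin-β LTB (5.13 ± 0.12), the ubiquitin-like modifier UBD (5.01 ± 0.15), TNFRSF9, which encodes 4-1BB (4.12 ± 0.13), and ART3 (3.91 ± 0.38). OR2I1P is uncertain, since it overlaps UBD on the other strand of chromosome 6 (29550407 to 29557721 against 29555515 to 29559732) and whether the counting used strand is not given.

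Of the gene lists, NF-κB targets rose as a group with TNF, 32 of 34 tested members higher and 0 lower (33 higher adjusted over the list alone), with a median log2 of 1.74. TNFAIP2 (3.22 ± 0.08) was among them. Chemokines and cytokines rose in 23 of 27 with 0 lower (23 higher and 1 lower adjusted over the list alone), among them IL32 (2.92 ± 0.08), CSF1 (3.23 ± 0.10) and CXCL11 (3.74 ± 0.18). Members of the non-canonical NF-κB pathway rose in 8 of 13 (8 adjusted over the list alone), with RELB at 2.57 and NFKB2 at 1.85. Antigen presentation rose in 19 of 20 (19 adjusted over the list alone, median 0.59), including the peptide transporter TAP1 (1.54 ± 0.07), its partner TAPBP (1.08) and the immunoproteasome subunit PSMB9 (1.56). Immune surface molecules rose in 11 of 18 and fell in 1 (11 and 1 adjusted over the list alone), with the ligand ICOSLG at 2.10 and CD40 at 1.46. Matrix proteases and their regulators rose in 7 of 14 (9 adjusted over the list alone), with the gelatinase MMP9 at 3.51 ± 0.12 and SERPINA3 at 3.35. The necroptosis list rose in 11 of 29 and fell in 1 (11 and 1 adjusted over the list alone, median 0.13), led by BIRC3 and TNFAIP3, followed by the deubiquitinase CYLD (0.99) and BIRC2 (0.83). Within it MLKL rose by 0.59 ± 0.08 (adjusted p = 4.35e-04), while RIPK1 (0.10, adjusted p = 0.404) and CASP8 (0.12, adjusted p = 0.238) did not pass.

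Alveolar and club cell genes fell with TNF, 9 of 19 lower and 2 higher (11 and 2 adjusted over the list alone, median -0.27). HOPX (-1.37 ± 0.07) and the surfactant protein genes SFTPA1 (-1.56 ± 0.09) and SFTPA2 (-1.21 ± 0.11) fell, whereas the phosphate transporter SLC34A2 rose by 1.66 ± 0.13. Among single genes the lowest values were those of MYBPH (-3.28 ± 0.21), B3GNT6 (-2.43 ± 0.16), PRR15L (-2.42 ± 0.23), the prostaglandin transporter SLCO2A1 (-2.39 ± 0.29) and the keratins KRT4 (-2.10 ± 0.08) and KRT3 (-1.98 ± 0.38). KRT3 no longer passed without the control library that had no stimulation (-1.83, adjusted p = 0.0582). Camera, a competitive set test with a preset correlation of 0.01, called these 8 lists (adjusted p from 1.35e-193 for NF-κB targets to 3.49e-09 for alveolar genes), and all 8 hold with an estimated correlation (adjusted p from 0.00219 to 0.0491). Lists that camera also called and that lose the call with it include interferon-stimulated and apoptosis genes. Interferon-stimulated genes were higher in 35 of 47 with 0 lower (39 higher adjusted over the list alone), led by IRF1 (1.67) and GBP4 (3.69), with adjusted p = 0.119 with an estimated correlation. Apoptosis genes were higher in 10 of 29 and lower in 3 (11 and 3 adjusted over the list alone), with BCL2A1 at 2.47 and the death receptor FAS at 0.91, and adjusted p = 0.366 with an estimated correlation. Genes for 8 interferon ligands were too low to test, with at most 10 reads in any library, as was the necroptosis sensor gene ZBP1, with 2 to 10 reads. Markers of other cell types were few: 0 of 5 tested fibroblast genes passed with TNF (0 adjusted over the list alone), 1 of 8 endothelial genes rose and 1 fell (1 and 1 adjusted over the list alone), and 1 of 6 haematopoietic genes rose (1 adjusted over the list alone).

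In all, 2175 genes passed with TNF, 1297 higher and 878 lower, and 450 of them had an absolute log2 fold change of at least 1. Without the 2 libraries of lowest mitochondrial share it was 1601 higher and 1518 lower, so the excess of higher calls depends on these, and CASP8 passed there (0.19, adjusted p = 0.0298). Treating the RIPK3 siRNAs as replicates of 1 group, with no replicate block for the siRNA, left 642 (484 higher and 158 lower), and in that fit MLKL and KRT3 no longer passed. The count was 1358 without the unstimulated control library, 1382 without the control library with TNF, and 1371 and 1400 without the unstimulated and the TNF library of RIPK3 siRNA 2.

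**Figure D2:**
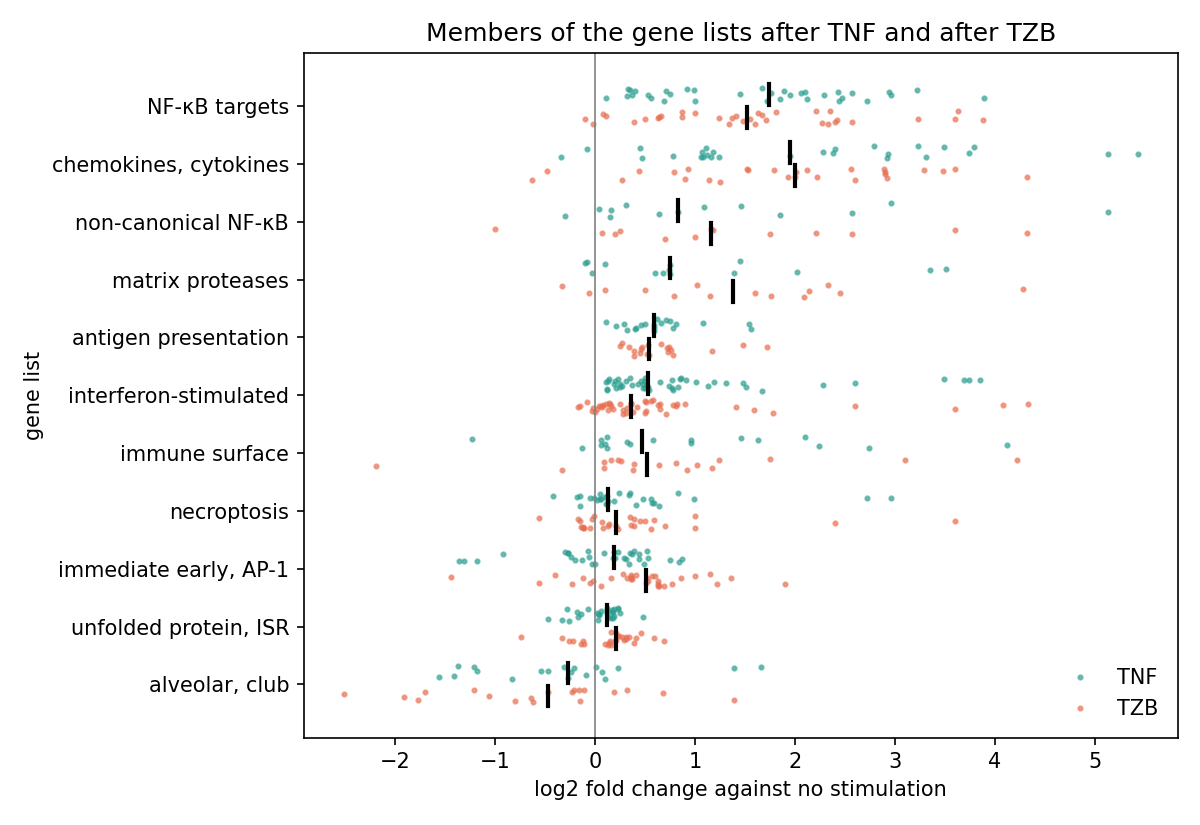
Log2 fold changes against no stimulation (horizontal axis) of the tested members of 11 gene lists (vertical axis) with TNF (green) and with TZB (orange). Each point is 1 gene averaged over the 3 siRNAs, black bars are medians, and points to the right of the grey line are higher than without stimulation. The median of NF-κB targets lies at 1.74 with TNF and 1.52 with TZB, and that of alveolar and club genes at -0.27 and -0.47.

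TZB against no stimulation measured the response to the necroptosis-inducing mix. NF-κB-driven inflammatory genes again led it. BIRC3 reached 629.4 ± 143.6 CPM (SD, n = 3), a rise of 3.60 ± 0.07 on the log2 scale (SE), with TNFAIP3 at 2.40 ± 0.07, NFKBIA at 2.35 ± 0.06 and CXCL8 at 2.00 ± 0.14. The highest named genes were OR2I1P (6.03 ± 0.16, uncertain as above), UBD (4.93 ± 0.15), the guanylate-binding protein gene GBP5 (4.33 ± 0.58), LTB (4.32 ± 0.12), MMP9 (4.28 ± 0.13) and TNFRSF9 (4.22 ± 0.13). GBP5 had only 7 reads over the 3 unstimulated libraries and 129 over those with TZB. The lowest were SLCO2A1 (-3.94 ± 0.34), MYBPH (-3.76 ± 0.23), KRT3 (-3.24 ± 0.44), PRR15L (-3.24 ± 0.25) and KRT4, which fell from 131.9 ± 42.1 to 15.8 ± 7.18 CPM (-3.10 ± 0.09). The antisense transcript LAMA4-AS1, uncertain because strand use is not given, had 629 reads over the 3 unstimulated libraries and 0 with TZB, at least 183.1-fold lower against a floor of 3 reads over the group. Its call depends on the siRNA term, since it did not pass with no replicate block.

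Of 29 necroptosis genes, 13 rose with TZB and 1 fell (13 and 1 adjusted over the list alone). MLKL rose by 0.59 ± 0.08 (adjusted p = 3.17e-04), and RIPK1 (0.08 ± 0.06, adjusted p = 0.416) and CASP8 (-0.05 ± 0.06, adjusted p = 0.633) did not pass. NF-κB targets rose in 30 of 34 (30 adjusted over the list alone). Chemokines and cytokines rose in 24 of 27 and fell in 2 (24 and 2 adjusted over the list alone), and non-canonical NF-κB genes rose in 9 of 13 (11 higher and 1 lower adjusted over the list alone). All 20 antigen presentation genes rose (20 adjusted over the list alone), with TAP1 at 1.72 and TAP2 at 0.74. Immune surface molecules rose in 13 of 18 and fell in 1 (13 and 1 adjusted over the list alone). Matrix proteases rose in 10 of 14 and fell in 1 (10 and 1 adjusted over the list alone), with a median of 1.37, and included the collagenase MMP13 (2.14), the urokinase gene PLAU (1.60) and MMP14 (1.02). Alveolar and club genes fell in 10 of 19 and rose in 2 (12 and 3 adjusted over the list alone), with HOPX at -1.91, SFTPA1 at -1.77, CEACAM6 at -1.70 and LPCAT1 at -1.06. These 8 lists passed camera (adjusted p from 1.96e-137 to 4.52e-11) and hold with an estimated correlation (adjusted p from 0.00367 to 0.0429).

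Other lists passed camera with TZB and lose the call with an estimated correlation. Immediate early and AP-1 genes were higher in 21 of 33 and lower in 1 (22 and 1 adjusted over the list alone), with FOSL2 at 1.22, the stress-induced factor ATF3 at 1.15, JUNB at 1.00 and KLF2 at -1.44, and adjusted p = 0.24 with an estimated correlation. Unfolded protein and integrated stress response genes were higher in 14 of 28 and lower in 4 (15 and 5 adjusted over the list alone), with PPP1R15A at 0.69 and CTH at -0.74, and adjusted p = 0.624 with an estimated correlation. Cholesterol synthesis genes were higher in 12 of 23 and lower in 1 (12 and 1 adjusted over the list alone), with SQLE at 0.79 and HMGCS1 at 0.60, and adjusted p = 0.57 with an estimated correlation. Interferon-stimulated genes were higher in 24 of 47 (28 adjusted over the list alone), with adjusted p = 0.402 with an estimated correlation. Apoptosis genes were higher in 10 of 29 and lower in 3 (10 and 3 adjusted over the list alone), also at adjusted p = 0.402 with an estimated correlation. Ribosomal protein genes were higher in 7 of 32 (8 adjusted over the list alone) with a median of only 0.14, and adjusted p = 0.642 with an estimated correlation.

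With TZB 3622 genes passed, 2048 higher and 1574 lower, of which 725 had an absolute log2 fold change of at least 1. Upper-quartile scaling gave 1662 higher and 1972 lower, so the balance of directions depends on the scaling, while the named genes and the 8 lists keep their sign. With no replicate block the count was 1216, and it was 2382 without the unstimulated control library, 2292 without the unstimulated and 2290 without the TZB library of RIPK3 siRNA 2. TNF and TZB shared 1856 of their calls in the same direction, 1119 higher and 737 lower, against 161.7 and 84.2 for independent lists, and 1 gene was called in opposite directions. Both comparisons use the same 3 unstimulated libraries. Simulated unchanged groups against those libraries gave at most 2 shared calls, a covariance of 0.0154 against 0.166 observed, and a correlation of 0.494 against 0.853, and part of the excess may come from the shared controls, which are too few to split.

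TZB against TNF isolates the 2 added drugs, zVAD-fmk and birinapant, which always came together and cannot be parted here. Single inducible genes were higher with the drugs. The AP-1 subunits FOSB and FOS were higher by 1.90 ± 0.29 (adjusted p = 0.00943) and 1.53 ± 0.26 (adjusted p = 0.0131). FOS had fallen with TNF, from 6.99 ± 2.62 to 3.04 ± 0.266 CPM, and stood at 8.78 ± 1.70 with TZB (SD, n = 3). The heat shock gene HSPA6 went from 2.56 ± 0.558 to 9.12 ± 0.624 CPM (SD, n = 3; log2 1.85 ± 0.17, adjusted p = 5.99e-04), and the growth factor gene HBEGF from 17.5 ± 0.761 to 36.1 ± 1.85 (1.05 ± 0.08, adjusted p = 5.89e-04). CCL5 (1.10 ± 0.16) and RASSF9 (1.21 ± 0.25) were also higher, as was BIRC3 (0.63 ± 0.06, adjusted p = 5.99e-04). CCL2 was lower with the drugs, at 1.93 ± 1.01 against 10.97 ± 4.95 CPM (log2 -2.53 ± 0.23, adjusted p = 5.99e-04). So were the tryptophan-degrading enzyme gene IDO1 (-1.32 ± 0.24), the pseudogene CYP2B7P (-1.51 ± 0.17, uncertain because of its near-identical relatives), RASSF4 (-1.24 ± 0.19) and TRERF1 (-1.23 ± 0.19). The readthrough transcript TM4SF19-DYNLT2B (-3.81 ± 0.80) shares exons with its neighbours and is uncertain. TNFAIP3 was lower by a small step (-0.31 ± 0.06, adjusted p = 0.0396). CXCL8 (-0.40 ± 0.13, adjusted p = 0.201), NFKBIA (-0.09, adjusted p = 0.512), MLKL (0.00 ± 0.08, adjusted p = 0.998), RIPK1 (-0.02, adjusted p = 0.951) and CASP8 (-0.17, adjusted p = 0.258) did not pass.

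Immediate early and AP-1 genes were higher with TZB than with TNF in 7 of 33 and lower in 0 (17 higher adjusted over the list alone, median 0.27), including the phosphatase gene DUSP1 (1.01 ± 0.11), ATF3 (0.76) and SPRED1 (0.41). Interferon-stimulated genes were lower in 6 of 47 and higher in 0 (22 lower adjusted over the list alone, median -0.19), including OAS2 (adjusted p = 0.00562), SAMD9L (-0.68), IFIT1 (-0.52) and OAS1 (-0.49). Camera called both (adjusted p = 3.21e-20 and 7.21e-15), but with an estimated correlation the adjusted p was 0.315 and 0.403. Chemokines and cytokines split, 2 higher and 3 lower of 27 (4 and 10 adjusted over the list alone), with CXCL1 at -1.14 and LTB at -0.81. Non-canonical NF-κB genes were higher in 3 of 13 and lower in 1 (4 and 1 adjusted over the list alone), with the kinase gene MAP3K14, whose product NIK is degraded through cIAP proteins, at 1.02 ± 0.11 and NFKB2 at 0.36. Heat shock genes were higher in 2 of 17 (2 adjusted over the list alone), HSPA1A (0.49) and HSPA1B (0.37), which are near-identical copies and so uncertain one by one. Matrix proteases were higher in 2 of 14 and lower in 1 (6 and 2 adjusted over the list alone), with MMP9 at 0.77, MMP13 at 0.75 and SERPINA3 at -1.02. Alveolar genes were lower in 2 of 19 (5 lower and 2 higher adjusted over the list alone), SLC34A2 (-0.97) and HOPX (-0.54). These 5 lists also passed camera and lost the call, with adjusted p = 0.315 to 0.426 with an estimated correlation. Unfolded protein response, glycolysis, cholesterol synthesis and ribosomal protein genes also passed camera. At most 1 member of each passed over all genes, and the adjusted p was 0.573 to 0.657 with an estimated correlation. The unfolded protein list had 1 of 28 higher (3 higher and 1 lower adjusted over the list alone). Glycolysis had 1 of 29 (2 adjusted over the list alone), cholesterol synthesis 0 of 23 (1 adjusted over the list alone) and ribosomal proteins 0 of 32 (0 adjusted over the list alone).

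TZB and TNF differed in 188 genes, 85 higher and 103 lower, of which 26 had an absolute log2 fold change of at least 1. This count is the least stable of the stimulation comparisons: it was 79 higher and 150 lower with upper-quartile scaling, 0 with no replicate block (edgeR, with 859 genes at an unadjusted p under 0.05), 354 by DESeq2, 687 with no filter on low counts, 311 on uniquely placed reads and 120 from the 6 libraries alone. Without 1 library it was 54 (control with TNF), 112 (control with TZB), 460 (siRNA 1 with TNF), 63 (siRNA 2 with TNF) or 29 (siRNA 2 with TZB), and it was 818 without the 2 libraries of lowest mitochondrial share. HBEGF, HSPA6, CCL2, BIRC3 and CYP2B7P passed whichever 1 library was left out. Without the whole RIPK3 siRNA 2 series BIRC3 (adjusted p = 0.056) and CYP2B7P (0.119) did not pass, and with no replicate block none of these genes did. FOSB lost its call without the TZB library of siRNA 2 (adjusted p = 0.0856). CCL5 and TRERF1 lost it without that library (0.0796 and 0.113) or the TNF library of siRNA 2 (0.0518 and 0.069), and FOS without either of these (0.122 and 0.0899) or the control libraries with TNF (0.0529) or TZB (0.0853). CXCL8 gained a call without the control library with TZB (-0.64, adjusted p = 0.021), with no filter on low counts (-0.41, adjusted p = 1.67e-06) and without the 2 libraries of lowest mitochondrial share (-0.57, adjusted p = 0.00626), where CASP8 did too (-0.26, adjusted p = 0.0409). With no filter the gain of CXCL8 came at almost the fold change of the main fit (-0.40). RASSF4 lost its call in 4 fits without 1 library, among them that without the control library with TNF (0.0842). IDO1, at -0.87 (0.119) without the 2 libraries of lowest mitochondrial share, lost it in 5 (control with TZB, 0.096), TNFAIP3 in 6 (siRNA 2 with TNF, 0.283). TM4SF19-DYNLT2B lost it in 7 (siRNA 2 with TNF, 0.247) and RASSF9 in all 9 (siRNA 2 with TZB, 0.284).

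**Figure D3:**
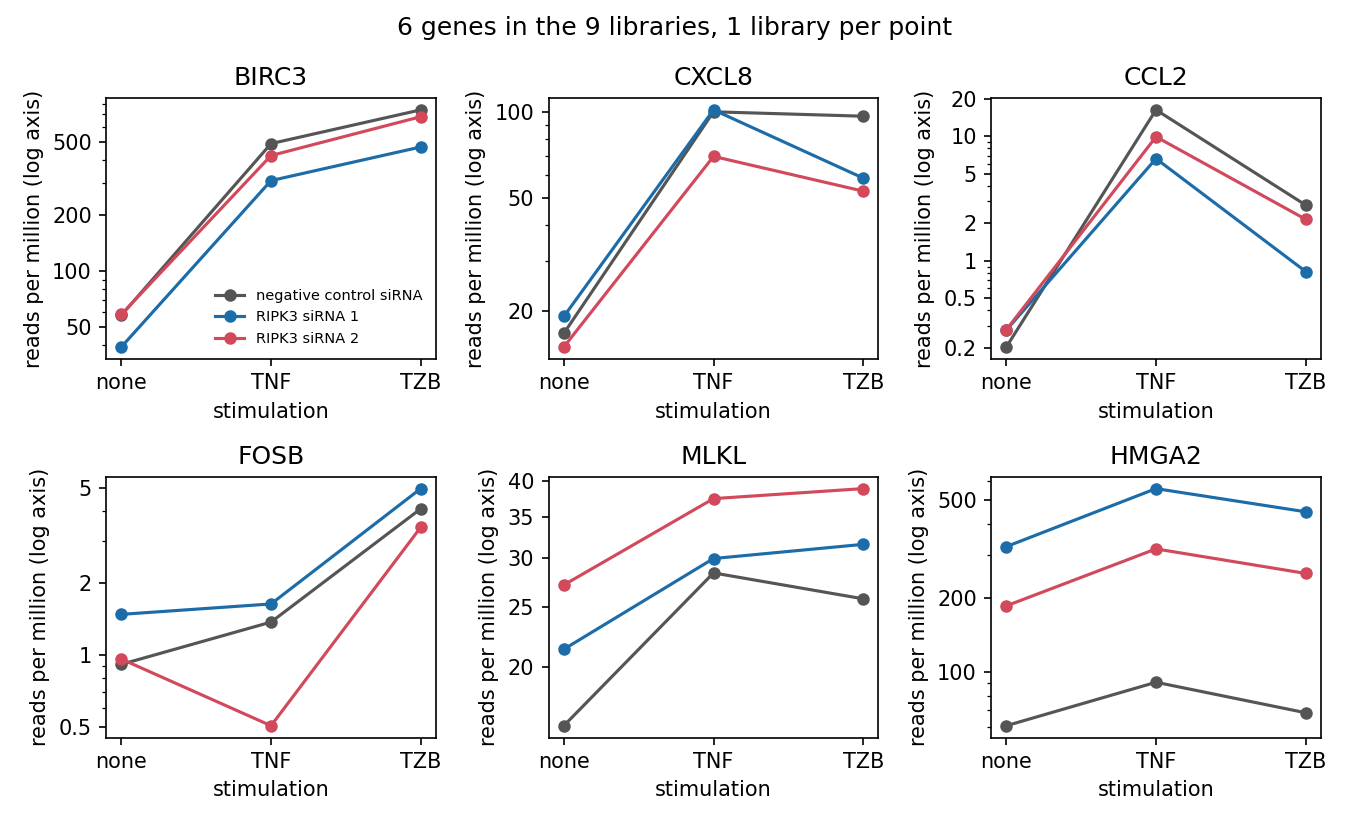
CPM (vertical axes, log scale) of 6 genes by stimulation state (horizontal axes), with 1 library per point and lines joining the libraries of the same siRNA. BIRC3 rose with TNF and further with TZB with each siRNA, CCL2 peaked with TNF, and HMGA2 lay higher with both RIPK3 siRNAs than with the control in each state.

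The RIPK3 siRNAs were compared with the negative control to learn what the knockdown changes across the 3 states. Beside RIPK3, the architectural chromatin gene HMGA2 stood at 442.8 ± 116.7 and 251.4 ± 65.4 CPM with siRNA 1 and siRNA 2 against 73.2 ± 15.8 with the control (SD, n = 3; mean log2 2.17 ± 0.06, adjusted p = 9.03e-09). STMN1, which encodes a microtubule-destabilising protein, stood at 183.2 ± 4.21 and 152.8 ± 10.1 against 52.0 ± 2.85 (1.69 ± 0.05, adjusted p = 9.03e-09). MAB21L4 was lower, at 7.13 ± 1.76 and 14.5 ± 7.31 against 34.3 ± 14.9 (-1.74 ± 0.10, adjusted p = 5.32e-07). MLKL was higher by 0.42 ± 0.07 (adjusted p = 0.00188), and RIPK1 was lower by a small step (-0.19 ± 0.05, adjusted p = 0.0327). The 3' untranslated regions of STMN1, MLKL, RAB3B and BIRC3 hold at least 1 of the 10 7-mers that went most with lower expression under the negative control siRNA. Those of RAB3B hold such a 7-mer of each RIPK3 siRNA as well and those of BIRC3 of siRNA 1. Those of TNFAIP3 hold a 7-mer of all 3 siRNAs, and it did not pass (0.09, adjusted p = 0.314). Those of HMGA2 and MAB21L4 hold none of the 10 of any of the 3 siRNAs. Of the 9463 genes searched, 3996 hold such a 7-mer of at least 1 siRNA, and the 7-mers were chosen on these same libraries. Holding one or none therefore does not decide why a gene changed. BIRC3 was lower with the RIPK3 siRNAs (-0.37 ± 0.05), not higher.

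Other genes that rose with the RIPK3 siRNAs were H2AC19 (2.27 ± 0.23, a histone gene with near-identical copies and so uncertain) and the vesicle GTPase gene RAB3B (1.80 ± 0.24). Those that fell included the heparan sulfotransferase gene HS3ST4 (-3.37 ± 0.55, though 10.73 CPM with unstimulated siRNA 1 against 10.95 in its control), the small RNA BCYRN1 (-1.87 ± 0.38) and the matricellular gene CCN2 (-1.62 ± 0.36). The readthrough transcripts TPTEP2-CSNK1E (3.30 ± 0.40) and PDCD6-AHRR (1.66 ± 0.49) share exons with their neighbours and are uncertain. On exon reads alone they did not pass, at 2.07 (adjusted p = 0.0627) and 1.56 (adjusted p = 0.0526). The mitochondrial tRNA gene MT-TA had 289, 197 and 117 reads with the control, 153, 0 and 0 with siRNA 1 and 0 in each library with siRNA 2, a short transcript that library preparation captures poorly. NF-κB targets were lower in 14 of 34 and higher in 2 (16 and 2 adjusted over the list alone, median -0.18), with RND1 at -1.12, TNFAIP2 at -0.65, BCL3 at -0.53, BIRC3 at -0.37 and NFKBIA at -0.24. Chemokines and cytokines were lower in 11 of 27 and higher in 1 (12 and 3 adjusted over the list alone, median -0.34), with CCL20 at -1.05, CXCL17 at -0.88, LTB at -0.73, IL32 at -0.55 and CXCL8 at -0.38 (adjusted p = 0.0408). NRF2 targets of the oxidative stress response were lower in 11 of 27 and higher in 0 (12 lower adjusted over the list alone, median -0.17), with the quinone reductase gene NQO1 at -0.41 and the glutathione synthesis gene GCLC at -0.35. Camera called these 3 lists (adjusted p = 9.24e-04, 0.00289 and 0.00289), and with an estimated correlation none held (adjusted p = 0.95, 0.745 and 0.745 with an estimated correlation).

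On average over both siRNAs 3034 genes passed, 1419 higher and 1615 lower, with 173 at an absolute log2 fold change of at least 1. With no replicate block 527 passed (362 higher and 165 lower), and MLKL, RIPK1, HS3ST4, CCN2, BIRC3, NFKBIA and CXCL8 were among the named genes that did not. The count was 1773 without the unstimulated control library and 1882 without the control library with TNF. CCN2 lost its call without the control library with TNF (adjusted p = 0.0553) or TZB (0.0761), and stood at -0.96 (0.0896) without the 2 libraries of lowest mitochondrial share. DESeq2 gave no adjusted p for CCN2, BCYRN1 and TPTEP2-CSNK1E and did not call PDCD6-AHRR (0.113), MT-TA (0.0562) or CXCL8 (0.149). Leaving out 1 library ended the call of PDCD6-AHRR in 5 such fits (unstimulated siRNA 2 library, 0.075), and of RIPK1 and CXCL8 in 6 each, among them that without the control library with TNF (0.176 and 0.0682). Without the control library with TZB, CXCL8 moved from -0.38 to -0.14 (adjusted p = 0.374).

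By siRNA, RIPK3 siRNA 1 changed 3521 genes (1751 higher and 1770 lower) and RIPK3 siRNA 2 changed 3281 (1527 higher and 1754 lower). Of these, 1130 passed in the same direction with both, 688 higher and 442 lower, against 162.8 and 189 for independent lists, and 226 passed in opposite directions against 351.6. Simulations without any siRNA effect gave at most 1 such gene, with a covariance of 0.0161 against 0.0637 observed and a correlation of 0.511 against 0.426. They leave out effects of the control siRNA itself, which both comparisons share. The overlap therefore does not show a common effect of RIPK3 loss, and part of the excess may come from the 3 shared control libraries. Unfolded protein response genes were higher with siRNA 1 in 12 of 28 and lower in 1 (15 and 1 adjusted over the list alone), the 1 list camera called for it (adjusted p = 1.45e-05, and adjusted p = 0.87 with an estimated correlation). With siRNA 2 camera called 10 lists, of which 0 held with an estimated correlation (smallest adjusted p = 0.404 with an estimated correlation). NF-κB targets were lower with siRNA 2 in 16 of 34 and higher in 2 (16 and 2 adjusted over the list alone), and chemokines and cytokines were lower in 13 of 27 and higher in 2 (13 and 2 adjusted over the list alone). With siRNA 1 camera called neither (adjusted p = 0.307 for both): NF-κB targets were lower in 7 and higher in 6 (8 and 6 adjusted over the list alone), and chemokines and cytokines lower in 6 and higher in 2 (6 and 2 adjusted over the list alone). Set directly against siRNA 1, siRNA 2 had medians of -0.21 for NF-κB targets and -0.32 for chemokines and cytokines. Camera called both there, but not with an estimated correlation (smallest adjusted p of any list = 0.483). The counts lean lower mainly with siRNA 2, and whether the siRNAs differ in these lists is not settled. The count for siRNA 2 was 1961 without the unstimulated control library and 1937, 1758 and 2133 without its own library with no stimulation, TNF and TZB. The shared count was 731 and 745 without the control library with no stimulation and with TNF, and 729 and 740 without those of siRNA 2.

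Set against each other, the RIPK3 siRNAs differed in 4516 genes, 2110 higher and 2406 lower with siRNA 2, which is more than either differed from the control. Glycolysis and hypoxia genes were lower with siRNA 2 in 22 of 29 and higher in 1 (23 and 1 adjusted over the list alone, median -0.35), with NDRG1 at -0.96, PFKFB4 at -0.83, VEGFA at -0.80 and PFKFB3 at -0.70. Unfolded protein response genes were lower in 16 of 28 and higher in 2 (19 and 2 adjusted over the list alone), with the co-chaperone gene DNAJC3 at -0.97 and CRELD2 at -0.60. Immediate early genes were lower in 17 of 33 and higher in 1 (22 and 1 adjusted over the list alone), with KLF6 at -0.66. Antigen presentation genes were lower in 11 of 20 (12 adjusted over the list alone), with ERAP1 at -0.87. Cell cycle genes were higher in 18 of 40 and lower in 4 (21 and 5 adjusted over the list alone), with the replication helicase genes MCM4 at 0.60 and MCM6 at 0.58. Camera called 9 lists here and 0 held with an estimated correlation (smallest adjusted p = 0.483 with an estimated correlation). The count was 2722 without the TNF library of siRNA 2, below the 3138 of siRNA 1 against the control in that fit. It was 3668 without the TNF library of siRNA 1, below the 3914 of siRNA 2 against the control. The order of these counts thus depends on single libraries.

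The interaction of knockdown and stimulation asked whether the responses to TNF and to TZB differ when RIPK3 is low. No gene passed for the TNF response, the TZB response or the difference between them by edgeR's quasi-likelihood test, with smallest adjusted p of 0.126, 0.192 and 0.0812. At an unadjusted p under 0.05 there were 483, 1111 and 1004 genes, where 821.2 would be below it by chance, and DESeq2 called 1, 2 and 14. The genes with the smallest p for the TZB response were the antisense transcript SLC9A3-AS1 (1.71 ± 0.24, adjusted p = 0.192, uncertain), SLC22A31 (0.73 ± 0.12), the cold-inducible RNA-binding protein gene CIRBP (0.89 ± 0.16), VSIG1 (-0.85 ± 0.14) and the readthrough transcripts POC1B-GALNT4 (-2.46 ± 0.40) and BCL2L2-PABPN1 (-1.15 ± 0.20), the last 5 at adjusted p = 0.259. CXCL8 was -0.81 ± 0.18 (adjusted p = 0.385), while BIRC3 (-0.12 ± 0.12, adjusted p = 0.856), TNFAIP3 (0.03 ± 0.14, adjusted p = 0.975), NFKBIA (0.07 ± 0.12, adjusted p = 0.928) and MLKL (-0.14 ± 0.15, adjusted p = 0.86) did not pass. The 6 genes of smallest p and CXCL8 passed with no filter on low counts (adjusted p up to 1.8e-04), without the TNF library of siRNA 1 (up to 0.00284) or siRNA 2 (up to 0.00719), and without the TZB library of siRNA 2 (up to 0.0368). SLC9A3-AS1 and BCL2L2-PABPN1 also passed without the TZB library of siRNA 1 (0.0477 and 0.00643). Several of these values rest on 1 control library. In that with TZB, SLC9A3-AS1 stood at 3.89 CPM against 11.02 and 8.81 with RIPK3 siRNA 1 and 2 and TZB. CIRBP stood there at 31.7 against 64.3 and 60.95, and CXCL8 at 96.4 against 58.5 and 52.7. BCL2L2-PABPN1 stood apart in the unstimulated control library instead, at 16.6 against 31.8 and 37.4. Among the 269 genes with a mean of at least 1 CPM that rose at least 2-fold with TNF, the median response was 1.36 with the control siRNA, 1.41 with RIPK3 siRNA 1 and 1.30 with RIPK3 siRNA 2. Among the 294 such genes that rose as much with TZB it was 1.28, 1.39 and 1.29. Among the 231 that fell as much with TZB it was -1.17, -1.07 and -1.15. All these genes were picked because they passed on average over the same siRNAs, in a fit that counts differing responses as spread. Genes whose response changes with knockdown are thus less likely to be among them. The medians therefore cannot decide whether the responses differ when RIPK3 is low.

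In the interaction of knockdown with the step from TNF to TZB, mitochondrially encoded mRNAs had a median of 1.09 over 13 genes. Of these 0 passed over all genes and 12 were higher adjusted over the list alone, with MT-CO3 at 1.38 ± 0.28 (adjusted p = 0.308) and MT-ND1 at 1.21 ± 0.25 (adjusted p = 0.301). These libraries differ in their mitochondrial share: 2.27% of reads in the control library with TZB and 2.63% in that of siRNA 1 with TNF, against 3.33% to 4.26% in the other 7. Interferon-stimulated genes had a median of 0.34 in the same interaction, with 0 of 47 passing (3 higher adjusted over the list alone). Camera called 4, 7 and 7 lists in the 3 interactions, and 0 held with an estimated correlation (smallest adjusted p = 0.954, 0.897 and 0.854 with an estimated correlation). The control arm has 1 library per state and is assumed to vary like the others. In simulated counts the same fit recovered 82% of genes changed 2-fold and 32% of those changed 1.5-fold, so most differences of 1.5-fold would be missed, and smaller ones were not simulated. Those counts held 200 changed genes and no other siRNA or stimulation effect, so they do not give the share recovered in the real data. In the real counts POC1B-GALNT4 (log2 -2.46) and SLC9A3-AS1 (1.71) did not pass, so the lack of calls does not exclude changes of 2-fold or more. With no filter on low counts the interactions called 108, 205 and 275 genes. That fit also took the adjusted p of RIPK3's own fall (edgeR) from 7.33e-06 to 2.75e-59 at the same log2 of -3.53. Leaving out 1 library of a RIPK3 siRNA leaves 1 residual degree of freedom and called between 1 and 373. The counts were 2, 1 and 9 without siRNA 1 unstimulated, 33, 242 and 80 without siRNA 1 with TNF, 33, 17 and 29 without siRNA 1 with TZB. They were 11, 12 and 10 without siRNA 2 unstimulated, 196, 160 and 373 without siRNA 2 with TNF, and 34, 70 and 147 without siRNA 2 with TZB.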

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

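The tests here were set up once the counts of genes were known, and those chosen only after their own result or the 7-mers were seen were the reading of shifted pairs for the control siRNA, the counts of genes without a site, and both tests of the mitochondrial pattern.

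The RIPK3 siRNAs stood out because the direct test of their difference called 4516 genes, and because 9 gene lists differed between them by both camera and fry. The list medians with siRNA 2 relative to siRNA 1 were -0.21 for antigen presentation, 0.16 for cell cycle, -0.32 for chemokines and cytokines, -0.35 for glycolysis and hypoxia, -0.35 for immediate early genes, -0.18 for matrix proteases, -0.21 for NF-κB targets, -0.26 for non-canonical NF-κB and -0.31 for the unfolded protein response. None of the 9 held in camera with an estimated correlation (adjusted p from 0.483 to 0.678).

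An siRNA can silence transcripts that match its seed, and both RIPK3 siRNAs left a trace of that kind. The siRNA sequences were not given in the sources used here, so the 7-mers could not be compared with the real seeds, and a site below means 1 of the 10 lowest 7-mers of an siRNA, found in these same libraries. With RIPK3 siRNA 1 the 7-mer TAACGAA in 3' untranslated regions went with lower expression at z = -12.65, where the lowest of 100 permutations was -5.39, and 5 of the 10 lowest 7-mers were 1-base shifts of it. With RIPK3 siRNA 2 it was TAACGTA at z = -18.56 (permutations to -5.02), with 3 such shifts, whereas the lowest 7-mers for TNF and TZB (z = -3.66 and -4.03) lay within their permutations. Seed matches may therefore explain part of the difference between the siRNAs. Of 5467 genes without a site of any of the 3 siRNAs 1956 differed, a count that does not size the effect, since sites were chosen on the same differences and other sequences may match, and secondary changes and the depth of the knockdown remain untested. The 10 ways to split the 6 libraries are too few for a share under 0.05: the real split called 4516, 1 of the 10 reached that count, and the highest other called 0. The other splits mix the RIPK3 siRNAs and leave their difference in the spread, so the 0 is no separate support.

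The same search bears on the 3034 genes that changed on average with the RIPK3 siRNAs. With the negative control siRNA the lowest 7-mer was GACAGTA at z = -12.91, against -5.28 in permutations. The criterion set in advance asked for a shifted 7-mer among the 10 lowest and did not say of which 7-mer. Read as shifts of the lowest one, as it was applied, there were 0 and a seed trace stays undecided. Read as any shifted pair, 11 pairs among the 10 were shifts of each other and 6 held GACGTA, a reading of the same z of -12.91 made afterwards. Release from the control siRNA may thus account for part of what rose, which these values leave open. Of the 9463 genes searched 2500 passed in either direction, 1177 of them among the 5467 without a site of any of the 3 siRNAs, which does not size it either. Loss of RIPK3 itself stays open, because no rescue or further control was sequenced in these libraries.

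Other splits of the 9 libraries into 3 and 6 point to the siRNA as the structure. In fits without the siRNA term, the control against the rest called 527 genes, and 3 of 81 splits reached that count: the real one and those that set apart siRNA 1 (1549 genes) or siRNA 2 (1059), while each other split called 0. Of 84 splits drawn, 81 could be fitted. Splits that break up a series leave the siRNA differences in the spread, so the low share shows that libraries of 1 siRNA go together. With whole series as the unit all 3 divisions reached 527, and the control did not stand further from the RIPK3 siRNAs than either of these stood from the rest.

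For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split and the highest other called 2175 and 0 genes for TNF, 3622 and 0 for TZB, 188 and 4 for TZB against TNF, 3521 and 0 for RIPK3 siRNA 1, and 3281 and 0 for RIPK3 siRNA 2, and in each case 1 of the 10 reached the real count. Each other split mixes the groups compared and leaves any difference between them in the spread. Its low count is therefore no separate support.

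Mitochondrially encoded mRNAs were low in the control library with TZB (2.27% of reads) and in that of siRNA 1 with TNF (2.63%), which drives the list's value in the interaction. Stimulation alone does not account for it, since the other libraries of those states lay at 3.56% or above, over the lowest unstimulated library (3.33%). Over the 9 libraries the mitochondrial share followed the intron share (Pearson r = 0.896, exact permutation p = 0.00668; Spearman rho = 0.817, p = 0.0108; 1 relation computed, two-sided), which is consistent with a difference in library preparation or RNA recovery. Without those 2 libraries r was 0.45 over 7, so the relation rests largely on them, and a biological difference between single libraries remains untested.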

How the results depend on the processing

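Exon reads only, no mitochondrial genes, the fits without the 2 libraries of lowest mitochondrial share and the counts of genes without a site were chosen after the data were seen; all other settings were planned. The fall of RIPK3 kept its direction and its call in every setting. RLE and upper-quartile scaling, exon reads and removal of mitochondrial genes left each count of calls within 1.5 times. Of 1843 comparisons of 92 named results, 1680 kept their call or lack of one, 127 lost the call and 36 gained it. Where a result was called in the main or the alternative fit, 0 reversed in direction. Results called in neither were not compared for direction. The interactions rest on 1 control library per state.

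With no filter on low counts, TZB against TNF rose to 687 and the interactions (TNF, TZB, TZB against TNF) to 108, 205 and 275, of which 105, 202 and 273 were among genes of the original filter. The low-count genes added are the only change in that fit, and how they alter the calls of other genes was not tested. The fall of RIPK3 kept its log2 of -3.53 there, while its adjusted p in edgeR's test went from 7.33e-06 to 2.75e-59. Calls gained with no filter thus cannot be told apart from a smaller estimated spread at like fold changes. DESeq2 gave 354, 1, 2 and 14, and unique reads 311 and, for the TNF interaction, 2. With no replicate block, TNF gave 642, TZB 1216, TZB against TNF 0 and the RIPK3 siRNAs 527, because differences between these siRNAs then count as spread. At an unadjusted p under 0.05 the 0 for TZB against TNF had 859 genes, and the interactions, each at 0 with edgeR, had 115, 253 and 340. It was not run for single RIPK3 siRNAs, which it joins. A log2 change of at least 1 left, by construction, 450, 725, 26, 173, 319 (siRNA 1), 235 (siRNA 2), 350 (siRNA 2 against 1) and 59 (both). The 6 libraries alone gave 120 for TZB against TNF. Without the 2 libraries of lowest mitochondrial share that comparison gave 818 and the TNF interaction 36; the cause was not tested. Genes without a site, fewer by construction, gave 1177 (mean), 1389 (siRNA 1), 1350 (siRNA 2), 1956 (siRNA 2 against 1) and 396 (both, 179 higher and 217 lower). Since sites were chosen on these libraries, that shift toward lower calls is partly built in.

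Camera with an estimated correlation called 8 lists for TZB and 0 for TZB against TNF, for each siRNA contrast and each interaction. Fry called 0 for TZB against TNF and the interactions, 5 for the mean of the RIPK3 siRNAs, 3 for siRNA 1 and 14 for siRNA 2 against 1.

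Leaving out 1 library or 1 siRNA series gave 950 to 2357 genes for TNF, 1628 to 4169 for TZB, 16 to 526 for TZB against TNF, 1773 to 3688 for the RIPK3 siRNAs, 2359 to 3263 for siRNA 1, 1758 to 4110 for siRNA 2, 2722 to 4794 for siRNA 2 against 1, 729 to 1278 for both, and 0 to 196, 0 to 242 and 0 to 373 for the interactions. The lowest counts for the 3 stimulation comparisons came without the RIPK3 siRNA 2 series. Contrasts that need the library or series left out gave no value.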

Other observations

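Single genes in this part were chosen after their values were seen, apart from the fixed gene lists, and no further test was added. With TZB 3 metallothionein genes were lower than with TNF alone: MT1E (-0.77 ± 0.10, adjusted p = 0.00476), MT2A (-0.55 ± 0.09, adjusted p = 0.0114) and MT1X (-0.50 ± 0.09, adjusted p = 0.0167), genes for small metal-binding proteins. With GCLC they were the 4 of 27 NRF2 targets that passed, all lower (5 lower and 1 higher adjusted over the list alone), and camera did not call that list (adjusted p = 0.253, median 0.05). Several NF-κB targets parted in the same comparison. TRAF1 (0.94 ± 0.11, adjusted p = 0.00177), RNF19B (0.77 ± 0.08, adjusted p = 0.00138) and the prostaglandin synthase gene PTGS2 (0.84 ± 0.13, adjusted p = 0.01) were higher with TZB, whereas ICOSLG (-0.86 ± 0.10, adjusted p = 0.00191) and BCL3 (-0.31 ± 0.06, adjusted p = 0.0479) were lower. Of the list's 34 members 5 were higher and 4 lower (6 and 9 adjusted over the list alone). The epithelial factor gene ELF3 (-0.70 ± 0.07), the protease gene TMPRSS2 (-0.97 ± 0.10) and complement C3 (-0.92 ± 0.13, adjusted p = 0.00573) were lower as well. With no replicate block none of the 16423 genes passed in this comparison (edgeR, with 859 at an unadjusted p under 0.05, and DESeq2 with the siRNA term called 354).

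The RIPK3 siRNAs changed several epithelial genes. E-cadherin CDH1 (-0.75 ± 0.06, adjusted p = 1.08e-05) and the keratins KRT8 (-0.55 ± 0.05), KRT7 (-0.44 ± 0.05), KRT19 (-0.36 ± 0.06) and KRT18 (-0.19 ± 0.05) were lower, and the tight junction gene CLDN1 was higher (1.31 ± 0.08, adjusted p = 6.52e-07). In the epithelial and mesenchymal list 8 of 28 were lower and 2 higher (9 and 2 adjusted over the list alone), which camera did not call (adjusted p = 0.185). With siRNA 2 the list had 9 lower and 1 higher (10 and 1 adjusted over the list alone), and with siRNA 1 it had 9 lower and 7 higher (9 and 7 adjusted over the list alone). In the direct comparison 12 were lower and 3 higher with siRNA 2 than with siRNA 1. There 0 lists held in camera with an estimated correlation, so the lean to lower values is not assigned to either siRNA. The ferroptosis suppressor gene GPX4 (-0.58 ± 0.06, adjusted p = 4.84e-05) was lower, and CD274, which encodes PD-L1 (0.72 ± 0.07, adjusted p = 3.5e-05), the anti-apoptotic gene MCL1 (0.73 ± 0.05, adjusted p = 1.7e-06) and the cell cycle inhibitor gene CDKN1A (0.83 ± 0.09, adjusted p = 6.5e-05) were higher. MUC1 was lower (-0.98 ± 0.07) and SFTPA1 higher (0.99 ± 0.08), so alveolar and club genes did not move one way (6 of 19 higher and 2 lower, 7 and 4 adjusted over the list alone).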
